A study of Mus musculus with 9 samples.

How the data were processed

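Expression was measured in mouse uterus with the QuantSeq 3' mRNA-Seq kit from 500 ng of total RNA per library, in 3 groups of 3 labelled samples each: saline, Endo-UdECM and Whole-UdECM in a thin endometrium model. The deposited table holds raw counts per gene row for each library, made by the authors with Bowtie2 and bedtools on the mm10 genome, with versions, strand and counting filters not given in the sources used here. It also holds log2 values, which per the file headers are normalised data, and for which the authors name TMM and CPM normalisation. Checked on the file, these deposited log2 values equal log2 of CPM plus 1 with TMM-scaled library sizes. The fold changes deposited by the authors are ratios of the group means of the anti-logged log2 values. The deposited p-values are unadjusted, and the test behind them is not given in the sources used here.

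The table's short column names were matched to the sample titles by the initials of group and treatment and the replicate number, which assigned 7 of its libraries. The treatment description uses 1 code for both preparations, so which preparation a column holds rests on that match. A further 6 columns, for 3 libraries that no label describes, were not used. Saline replicate 2 and Endo-UdECM replicate 1 have no column and were not analysed here. The plan assumed 9 libraries, so the fit used 7, with 4 residual degrees of freedom. The rule that 3 libraries of a group lie beyond 3 of another became that all libraries of a group lie beyond all of the other.

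The table has 23282 rows, of which 5191 are 0 in all 7 libraries, and 44 repeated symbols. Genes were kept by filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 15124. Libraries were scaled by TMM and fitted with edgeR's robust quasi-likelihood model with 1 mean per group, and the common biological coefficient of variation was 0.417. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in 4 comparisons: each preparation against saline, the preparations against each other, and their mean against saline. Standard errors of log2 fold changes were back-calculated from the test, as the absolute log2 fold change over the square root of the F statistic. They are not a separate estimate of precision. Levels are TMM-scaled CPM with the SD between libraries. Where a group had 0 counts, the fold of a single gene is a lower bound against a floor of 3 counts over the group, unless it is stated to be fitted. List medians and quartiles use fitted values.

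The 40 gene lists held 837 members, of which 828 were found by exact symbol and 766 were tested. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with adjustment over the lists of each comparison. Another 5 lists were written after the data were seen. Those with at least 3 members tested were adjusted among themselves alone, apart from the 40 lists. The overlap of the responses was set against 20 simulations of unchanged groups that share their saline libraries.

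Named genes were chosen by a rule. In each comparison it takes the 12 largest increases and 12 largest decreases among called genes whose groups do not overlap and whose mean is at least 10 counts per library. Where no gene passes in a direction, it takes the 4 of lowest p and states that they did not pass. It adds up to 4 members of lowest p from each called list, in the direction of the list, and a fixed set of genes of uterine biology. Of that set Tgfb1 was not tested, with 8 and 7 counts in Whole-UdECM replicates 1 and 2 and 0 in the other 5 libraries. Unnamed predicted transcripts were left out. Genes cited outside the rule were chosen after their values were seen.

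The procedure was tested on simulated data with the same libraries and depths. Of genes changed 2-fold it recovered 12, 14, 16 and 35% in Endo-UdECM against saline, Whole-UdECM against saline, Endo-UdECM against Whole-UdECM and the mean against saline, and of genes changed 4-fold 64, 70, 76 and 82%. It called 4, 6, 8 and 20 unchanged genes. In each comparison 100 genes were changed at each fold, drawn from genes above the lowest quartile of mean level. The simulated spread of a gene was the same in all groups, although the real saline pair differed more than the other pairs of 1 group. Recovery and false calls with the real saline libraries can therefore differ from these values.

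Leaving out a saline or Endo-UdECM library leaves 1 in that group, which is assumed to vary like the other groups. Alternatives tried were the replicate number as a block, leaving out each library, scaling by DESeq2 size factors or by library size alone, a weaker and a stricter count filter, DESeq2 1.42.0, limma-voom, limma-trend on the authors' log2 values, only the compared groups in the fit, a 2-fold minimum, an estimated correlation between genes, and fry. Chosen after seeing the data were the removal of the pancreas genes and Rn45s, a fit that is not robust, and the overlap without saline replicate 3. Depth was 8632708 to 11000193 counts per library, intervals of shares are 95% Clopper-Pearson intervals, and intervals and floors cover counting error only, since reads are not independent molecules.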

Results

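Gene expression was measured in mouse uterus by QuantSeq, which sequences the 3' ends of polyadenylated transcripts. The uteri came from a model of thin endometrium in which 95% ethanol was placed in the uterine cavity. Uterus-derived decellularised extracellular matrix (UdECM), the matrix left when the cells of a tissue are removed, was given 4 days later, and the control group is titled as saline treated. The labels name 2 preparations, Endo-UdECM and Whole-UdECM, and their making is not given in the sources used here. The labels list 9 samples, 3 per group, and the deposited columns cover 7 of them: saline replicates 1 and 3, Endo-UdECM replicates 2 and 3, and Whole-UdECM replicates 1, 2 and 3. Saline replicate 2 and Endo-UdECM replicate 1 were not analysed here. Total counts were 8994774 and 11000193 in saline replicates 1 and 3, 8632708 and 9670007 in Endo-UdECM replicates 2 and 3, and 9366567, 9419194 and 10268861 in Whole-UdECM replicates 1, 2 and 3. At these depths 3 counts, the limit that a count of 0 allows, correspond to 0.273 to 0.348 CPM, a unit of counts scaled to library size. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples. The comparisons, 40 gene lists and named-gene rule were chosen before the data were examined, except that the rule on groups that do not overlap was adapted to 7 libraries, and 5 further lists were written after the data were seen.

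The 2 saline libraries differed from each other more than any other pair of libraries of 1 group. Their log2 CPM values correlated across genes with r = 0.88, against 0.90 to 0.93 for the other 4 pairs of libraries of 1 group, and genes are not independent replicates. Saline replicate 1 correlated slightly more with each UdECM library (r = 0.878 to 0.889) than with saline replicate 3 (0.876). For saline replicate 3 the values with the UdECM libraries were 0.872 to 0.891. The controls thus differed from each other about as much as from the treated samples. Digestive enzyme transcripts of the exocrine pancreas made up 3.18% of the counts of saline replicate 3 (95% Clopper-Pearson interval 3.17 to 3.19%, counting error only). Their share was 0.00441% in saline replicate 1 (0.00399 to 0.00487%) and at most 0.00120% in each UdECM library. Amy2a5, a pancreatic amylase, had 65655 counts in saline replicate 3 and 33 in saline replicate 1. The ribosomal RNA precursor Rn45s took 23.1 and 16.6% of counts in the saline libraries, 16.1 and 14.4% in the Endo-UdECM libraries and 15.9, 15.2 and 19.1% in the Whole-UdECM libraries. The first principal component (28.8% of variance) put the saline libraries at -79.8 and -72.2 and the UdECM libraries at 8.25 to 45.7. The second (22.9%) put saline replicates 1 and 3 at opposite ends, 75.2 and -83.4.

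Endo-UdECM was compared with saline to ask which uterine genes differed after this matrix was given to an injured uterus. Plat, which encodes tissue-type plasminogen activator, a protease that starts fibrin breakdown, rose 7.26-fold in Endo-UdECM (log2 fold change 2.86 ± 0.24, SE, n = 2 against 2). Its level was 98.5 ± 19.0 CPM against 13.6 ± 0.577 in saline (SD), and both Endo-UdECM libraries lay above both saline libraries (adjusted p = 0.000457, edgeR quasi-likelihood test). Plat (Entrez 18791, protein coding) lies on chromosome 8 from 22757722 to 22782848 in mm10. It was the 1 gene that passed of 15124 tested, while 1414 genes had an unadjusted p under 0.05 and 756.2 are expected by chance. Groups that do not overlap, as for Plat, were seen in 40.5% of all tested genes, and chance gives 33.3%. The count was 108 without saline replicate 1, 100 without saline replicate 3, 4 without Endo-UdECM replicate 2, 2 without Whole-UdECM replicate 2, 4 without Whole-UdECM replicate 3 and 146 by DESeq2.

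Several genes stood near the threshold in Endo-UdECM without passing it. Igfbp3, a carrier of insulin-like growth factors, had a log2 fold change of 3.41 ± 0.44 (SE, adjusted p = 0.0853), with 120 ± 2.56 CPM against 11.3 ± 3.18 in saline (SD, n = 2 and 2). Id3, a target of BMP signalling, had 1.72 ± 0.25 (adjusted p = 0.0853), and both Endo-UdECM libraries were above both saline libraries. The neutrophil-attracting chemokine Cxcl2 had 120 and 706 counts in Endo-UdECM replicates 2 and 3 and 0 in both saline libraries (adjusted p = 0.0868). Of the genes lower in Endo-UdECM, the 4 of lowest p were the orphan receptor Gpr153 (4.13-fold lower, adjusted p = 0.0868), the vault RNA Vaultrc5 (7.66-fold, 0.0868), the serine protease Htra1 (2.52-fold, 0.138) and the small RNA Rn4.5s (6.27-fold, 0.138). None of these passed, and each was lower in 2 of 2 libraries. The 16 genes named in advance and tested included no call. Igf1, an estrogen-induced growth factor, had a log2 fold change of -1.23 ± 0.30 (adjusted p = 0.28), and Mki67, a proliferation marker, -0.38 ± 0.38 (0.781).

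Some immune gene groups were higher in Endo-UdECM than in saline, while neutrophil (adjusted p = 0.0963), T and NK cell (0.574), mast cell and eosinophil (0.216) and interferon response genes (0.267) did not pass. All 27 measured macrophage markers had estimates above 0, with a median log2 fold change of 1.25 (adjusted p = 4.2e-08 by a set test with a preset correlation, camera). With an estimated correlation the adjusted p was 0.568 for this list and for the other lists that passed in this comparison unless another value is given. In Endo-UdECM replicates 2 and 3 the mean levels were -0.087 and 0.91 for macrophage, 0.090 and 0.73 for complement and -0.070 and 1.38 for inflammatory genes (centred log2 CPM), and saline lay at -0.84 and -0.68, -0.48 and -0.54, and -0.64 and -0.68. No macrophage marker passed singly over all genes tested or adjusted over the list alone. Csf1r, the receptor for the macrophage growth factor Csf1, had 1.59 ± 0.39 and the complement component C1qa 1.31 ± 0.42 (SE, n = 2 and 2, adjusted p = 0.322 and 0.401). The complement list had a median of 0.86 with 16 of 16 estimates above 0 (adjusted p = 1.63e-05), and 7 members were higher adjusted over the list alone against 0 over all genes. It shares C1qa, C1qb and C1qc with the macrophage list, so these lists are not independent. The list of dendritic cells and antigen presentation had a median of 0.97 (adjusted p = 4.51e-05), with 5 members higher adjusted over the list alone and 0 over all genes. Among them the class II genes H2-Ab1, H2-Aa and H2-Eb1 had log2 fold changes of 1.44 ± 0.28, 1.56 ± 0.33 and 1.43 ± 0.27. Inflammatory cytokines and chemokines had a median of 1.26 with 22 of 26 estimates above 0 (adjusted p = 0.000119), 3 higher adjusted over the list alone and 0 over all genes. This call was lost without Endo-UdECM replicate 3 (adjusted p = 0.204). B and plasma cell genes had a median of 1.72 over 9 members (adjusted p = 0.0398), none passing over the list alone or over all genes, and the median was 3.97 without saline replicate 1. That call was lost with the replicate block (0.0916) or without saline replicate 3 (0.185, median 3.17), Endo-UdECM replicate 3 (0.249), Whole-UdECM replicate 2 (0.124) or Whole-UdECM replicate 3 (0.0732).

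Signalling and tissue groups also moved in Endo-UdECM. WNT pathway genes had a median of 0.74 with 23 of 30 estimates above 0 (adjusted p = 9.84e-05, and adjusted p = 0.326 with an estimated correlation), with 2 members higher adjusted over the list alone and 0 over all genes. Its members included Sfrp2, a secreted WNT modulator, at 1.56 ± 0.36 (SE, n = 2 and 2). Progesterone-induced uterine genes had a median of 0.97, with 17 of 19 estimates above 0 (adjusted p = 0.000752), 3 higher adjusted over the list alone and 0 over all genes, and the median was 0.57 without saline replicate 1. Cyp26a1, a retinoic acid-degrading enzyme of that list, was at 0 in saline and at least 17.4-fold higher. Endothelial genes (median 0.62, adjusted p = 0.0001) had no member passing over the list alone or over all genes. Lymphatic endothelial genes had a median of 0.59 with 7 of 7 estimates above 0 (adjusted p = 0.00157), a call lost without saline replicate 3 (0.185). Smooth muscle genes of the myometrium had a median of 0.55 with 21 of 23 above 0 (adjusted p = 4.07e-05), lost without saline replicate 1 (0.12, median 0.22), and the median was 0.94 without saline replicate 3. Matrix proteases and inhibitors had a median of 0.55 (adjusted p = 0.00146), with Plat the 1 member passing over the list alone and over all genes, and the call was lost without saline replicate 3 (0.124), where the median was 1.02. Adipocyte genes had a median of 0.81 (adjusted p = 0.00187, lost without saline replicate 3 at 0.765, with a median of 0.19, and without Endo-UdECM replicate 3 at 0.182). The list of BMP and Hedgehog signalling had a median of 0.38 (adjusted p = 0.0398, and 0.571 with an estimated correlation), with 2 members higher adjusted over the list alone and 0 over all genes, and was lost without saline replicate 3 (0.575, median 0.21) or Endo-UdECM replicate 2 (0.785).

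Lower groups in Endo-UdECM were 3. Ribosomal protein genes had a median log2 fold change of -0.33 with 30 of 30 estimates below 0 (adjusted p = 3.42e-05, and adjusted p = 0.58 with an estimated correlation). Without saline replicate 1, the library with the highest Rn45s share, the median was -0.07 and the adjusted p 0.652, and without saline replicate 3 the median was -0.59. With library size alone, which moved the median of all genes from 0.02 to 0.24, the medians were -0.10 for ribosomal proteins, -0.10 for oxidative phosphorylation and 0.61 for BMP and Hedgehog signalling. Genes of oxidative phosphorylation had a median of -0.32 with 21 of 24 below 0 (adjusted p = 4.07e-05), and the ATP synthase subunit Atp5o had -0.69 ± 0.20 (SE). Erythrocyte genes had a median of -0.73 (adjusted p = 0.00109, and adjusted p = 0.571 with an estimated correlation), lost without saline replicate 3 (0.0602, median -0.48) or Endo-UdECM replicate 3 (0.525). Hbb-bs and Hbb-b1, near-identical beta globin genes that share reads, both had -1.09 ± 0.46. Hbb-bt and Hbb-b2, with near-equal counts in each library, had -1.01 and -1.02. The preset correlation treats such rows as nearly independent, so the adjusted p of 0.00109 can be too low. No member of these 3 lists passed over all genes or adjusted over the list alone. Cell proliferation genes did not pass in Endo-UdECM against saline (median -0.17, adjusted p = 0.267, and 0.892 with an estimated correlation). Their median was 0.26 without saline replicate 3, -0.45 without saline replicate 1, where the list passed as lower (adjusted p = 0.00306), and 0.04 when scaled by library size alone.

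Whole-UdECM was compared with saline to ask the same of the other preparation. Among single genes, Cenpf and Hmmr of cell division and Msmo1 of sterol synthesis fell, while Plat, Igfbp3 and the epithelial tight junction gene Cldn1 rose. Igfbp3 rose 12.2-fold (log2 fold change 3.61 ± 0.43, SE, n = 3 against 2, adjusted p = 0.0175), from 11.3 ± 3.18 CPM to 138 ± 61.4 (SD). Cldn1 rose 13.4-fold to 20.7 ± 4.41 CPM (adjusted p = 0.0175), Rassf10, a Ras association domain gene, 13.9-fold (0.0175), and Plat 7.66-fold to 104 ± 6.77 CPM (0.000216). In each of these genes 3 of 3 Whole-UdECM libraries lay above both saline libraries. Msmo1, a sterol methyl oxidase of cholesterol synthesis, fell 4.17-fold (log2 fold change -2.06 ± 0.28, SE, adjusted p = 0.0175), lower in 3 of 3 libraries. Cenpf, a centromere protein of dividing cells, had a log2 fold change of -1.50 ± 0.21 (adjusted p = 0.0175) and was lower in 3 of 3 libraries. Igfbp3 (Entrez 16009) lies on chromosome 11 from 7206091 to 7213923, Cldn1 (12737) on chromosome 16 from 26356646 to 26371839, Rassf10 (78748) on chromosome 7 from 112953960 to 112957460, and Msmo1 (66234) on chromosome 8 from 64718145 to 64733578, all protein coding genes in mm10.

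In all, 48 of 15124 genes passed in Whole-UdECM against saline, 16 higher and 32 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), and 2008 had an unadjusted p under 0.05. The balance of genes called Whole-UdECM vs saline turned to 20 higher and 10 lower with library size alone, and to 139 higher and 42 lower without saline replicate 3. In all 48 the groups did not overlap, as in 28.9% of all tested genes, where chance gives 20%. Further genes that rose were Bambi, a decoy receptor of the TGF-beta family (4.45-fold), Cdo1, a cysteine dioxygenase (4.07-fold), Id3 (3.07-fold), Mgp, an inhibitor of matrix calcification (3.02-fold), the cholesterol exporter Abca1 (2.98-fold), the growth factor receptor Fgfr2 (2.81-fold), the epithelial transcription factor Tfcp2l1 (2.78-fold) and the Notch ligand Jag1 (2.78-fold), with adjusted p of 0.0198 to 0.0412. Genes that fell included the mitotic genes Hmmr (5.20-fold), Racgap1 (4.04-fold), Nusap1 (3.96-fold) and Ube2c (3.94-fold) and Apitd1, a centromere protein (12.5-fold). Vaultrc5 (6.71-fold), Rn4.5s (4.80-fold), Gpr153 (4.03-fold), the sterol-regulated Tmem97 (4.32-fold) and the histone genes Hist1h2ac (3.84-fold) and Hist1h2ao (3.77-fold) also fell, with adjusted p of 0.0179 to 0.0475. Hist1h2ao overlaps the listed genes Hist1h2ap and Hist1h2br and shares reads with them, Nusap1 overlaps Oip5, and the Rn4.5s count made up 0.403 and 0.314% of the saline libraries. Without Whole-UdECM replicate 2 the count was 1, and that gene was Plat. The count was 504 without saline replicate 1, 181 without saline replicate 3, 17 without Endo-UdECM replicate 2, 16 without Endo-UdECM replicate 3 (44, 31, 16 and 15 of them among the 48), 540 by DESeq2 and 52 with the pancreas genes and Rn45s taken out, an alternative chosen after seeing the data.

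**Figure D1:**
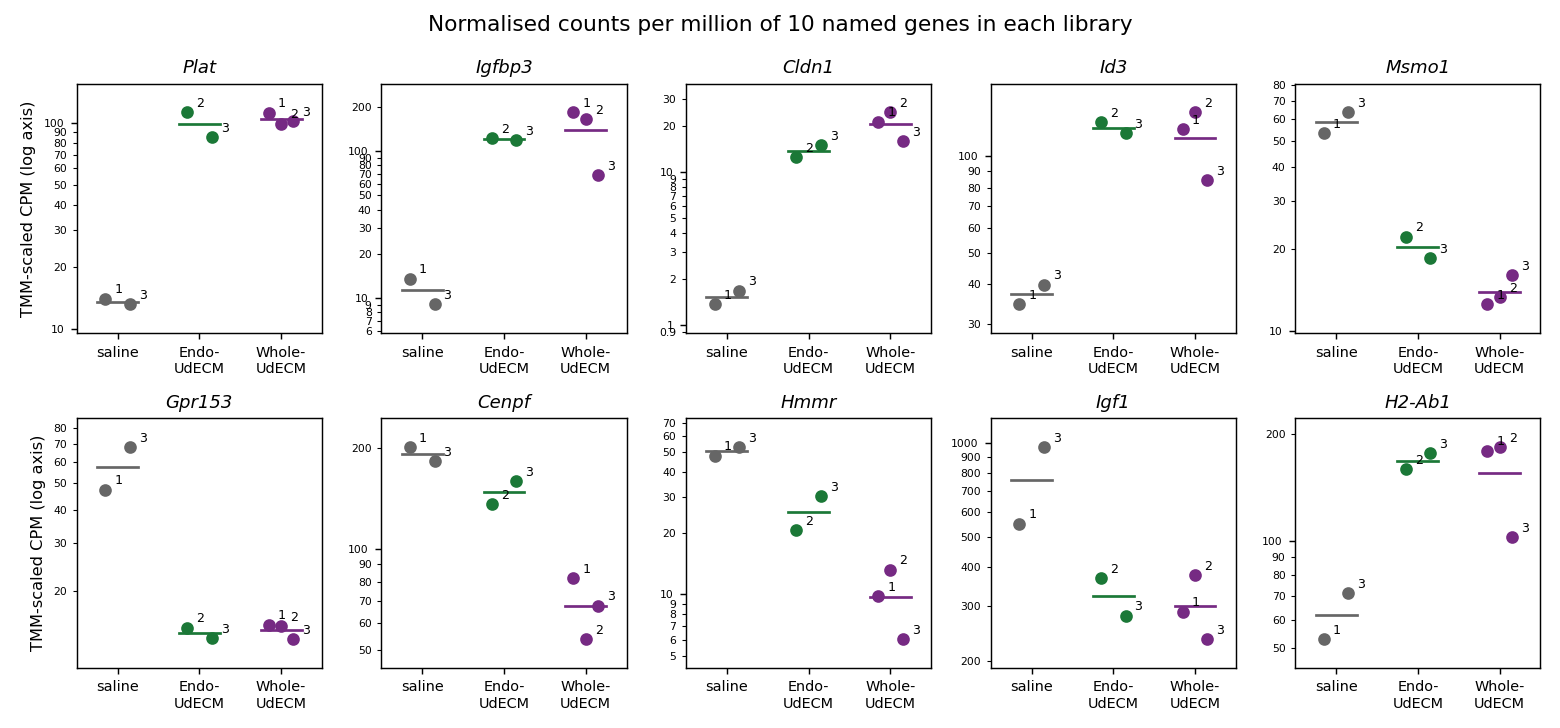
TMM-scaled CPM (log axis) of 10 named genes in each library, by group, with points numbered by replicate and bars at the group mean. Plat lay at 85.1 or more in each UdECM library, above both saline libraries, and Cenpf was lowest in the 3 Whole-UdECM libraries.

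Cell proliferation was the gene group with the lowest adjusted p in Whole-UdECM against saline. All 32 of its genes had estimates below 0, with a median log2 fold change of -1.51 (adjusted p = 1.78e-25, camera with a preset correlation, and adjusted p = 0.527 with an estimated correlation). Of these, 27 were lower adjusted over the list alone and 3 over all genes: Cenpf, Nusap1 and Ube2c. Mki67 had a log2 fold change of -1.70 ± 0.35 (SE, n = 3 and 2, adjusted p = 0.0738) and the mitotic cyclin Ccnb1 -1.75 ± 0.35 (adjusted p = 0.0562). The list's median was -0.91 without saline replicate 3, the library with pancreatic transcripts, where 1 saline library was left and its spread was taken from the UdECM groups. Genes of oxidative phosphorylation had a median of -0.39 with 23 of 24 below 0 (adjusted p = 2.78e-07, and 0.527 with an estimated correlation), 3 lower adjusted over the list alone and 0 over all genes. Fibrillar collagen and interstitial matrix genes had a median of -0.24 (adjusted p = 0.0345, and 0.758 with an estimated correlation), with 1 lower adjusted over the list alone and 0 over all genes. That call was lost with the replicate block (0.0734) or without saline replicate 3 (0.4, median -0.093), Endo-UdECM replicate 2 (0.0518), Endo-UdECM replicate 3 (0.0521) or Whole-UdECM replicate 3 (0.688). Estrogen-induced uterine genes had a median of -0.19 (adjusted p = 0.0234, and 0.62 with an estimated correlation), with 1 lower adjusted over the list alone, Igf1, at -1.34 ± 0.27, and 0 over all genes (adjusted p of Igf1 0.0562). That call was lost without saline replicate 3 (0.785), where the median was 0.028, Whole-UdECM replicate 1 (0.0965) or Whole-UdECM replicate 2 (0.103), and the median was -0.68 without saline replicate 1. With library size alone, which moved the median of all genes from 0.04 to 0.22, the medians were -0.059 for fibrillar collagen, -0.011 for estrogen-induced genes, -0.22 for oxidative phosphorylation and 0.48 for the IGF axis.

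Higher groups in Whole-UdECM were WNT, fat, macrophage, dendritic cell, complement and lymphatic genes. Inflammatory cytokine (adjusted p = 0.0541), neutrophil (0.985), T and NK cell (0.577), B and plasma cell (0.543), mast cell and eosinophil (0.332) and interferon response genes (0.985) did not pass. WNT pathway genes had a median of 0.85 with 24 of 30 above 0 (adjusted p = 8.12e-07, and 0.147 with an estimated correlation), 6 higher adjusted over the list alone and 0 over all genes. Sfrp2 had 1.76 ± 0.34 (SE, n = 3 and 2), the WNT receptor Fzd1 1.70 ± 0.45, and the WNT deacylase Notum had 52, 14 and 28 counts in the Whole-UdECM libraries and 0 in saline. Adipocyte genes had a median of 1.23 with 18 of 19 above 0 (adjusted p = 8.12e-07, and 0.534 with an estimated correlation), 4 higher adjusted over the list alone and 0 over all genes. Among them the fatty acid carrier Fabp4 had 2.23 ± 0.45 and lipoprotein lipase Lpl 1.30 ± 0.33. Macrophage genes had a median of 0.97 with 24 of 27 above 0 (adjusted p = 4.81e-05), and none passed over the list alone or over all genes. The list of dendritic cells and antigen presentation had a median of 0.79 (adjusted p = 0.00112), with 3 higher adjusted over the list alone and 0 over all genes, and complement had 0.67 (0.00259), with 2 and 0. The macrophage and complement lists share C1qa, C1qb and C1qc, and with an estimated correlation the adjusted p was 0.62 for each of these 3 immune lists. Their mean levels in Whole-UdECM replicate 3 (-0.55, -0.49 and -0.43 for macrophage, dendritic cell and complement genes, centred log2 CPM) were near those of saline (-0.84 and -0.68, -0.59 and -0.57, -0.48 and -0.54), while the other 2 Whole-UdECM libraries were at 0.23 to 0.81. Lymphatic endothelial genes had a median of 0.89 with 7 of 7 above 0 (adjusted p = 0.000173, and 0.527 with an estimated correlation), 6 higher adjusted over the list alone and 0 over all genes. The lymphatic receptor Lyve1 had 0.89 ± 0.25.

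Hormone and growth factor groups in Whole-UdECM were smaller in size. Progesterone-induced uterine genes had a median of 0.60 with 17 of 19 above 0 (adjusted p = 0.00114, and 0.541 with an estimated correlation), with 4 higher adjusted over the list alone and 0 over all genes, and the median was 1.00 without saline replicate 3. Cyp26a1 was at least 41.9-fold higher, and Fst, an activin-binding protein, had 3.45 ± 0.90 (SE, n = 3 and 2). The list of BMP and Hedgehog signalling had a median of 0.52 (adjusted p = 0.00112, and 0.62 with an estimated correlation), with 3 higher adjusted over the list alone and 1, Id3, over all genes. That call was lost without saline replicate 3 (0.157, median 0.31). The IGF axis had a median of 0.30 (adjusted p = 0.0279, and 0.595 with an estimated correlation), with 2 higher and 1 lower adjusted over the list alone and 1, Igfbp3, over all genes. It was lost without saline replicate 3 (0.253) or Whole-UdECM replicate 1 (0.0888). Matrix proteases and inhibitors had a median of 0.55 (adjusted p = 0.0066, and 0.62 with an estimated correlation), with Plat the 1 member passing over the list alone and over all genes. It was lost without saline replicate 3 (0.124) or Whole-UdECM replicate 1 (0.157). Endothelial genes had a median of 0.42 (adjusted p = 0.0345, and 0.751 with an estimated correlation), none passing over the list alone or over all genes. That call was lost with the replicate block (0.0865) or without saline replicate 1 (0.309), Whole-UdECM replicate 1 (0.319) or Whole-UdECM replicate 2 (0.145). The level of Whole-UdECM replicate 3 (-0.38) lay between the saline libraries (-0.67 and -0.18).

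**Figure D2:**
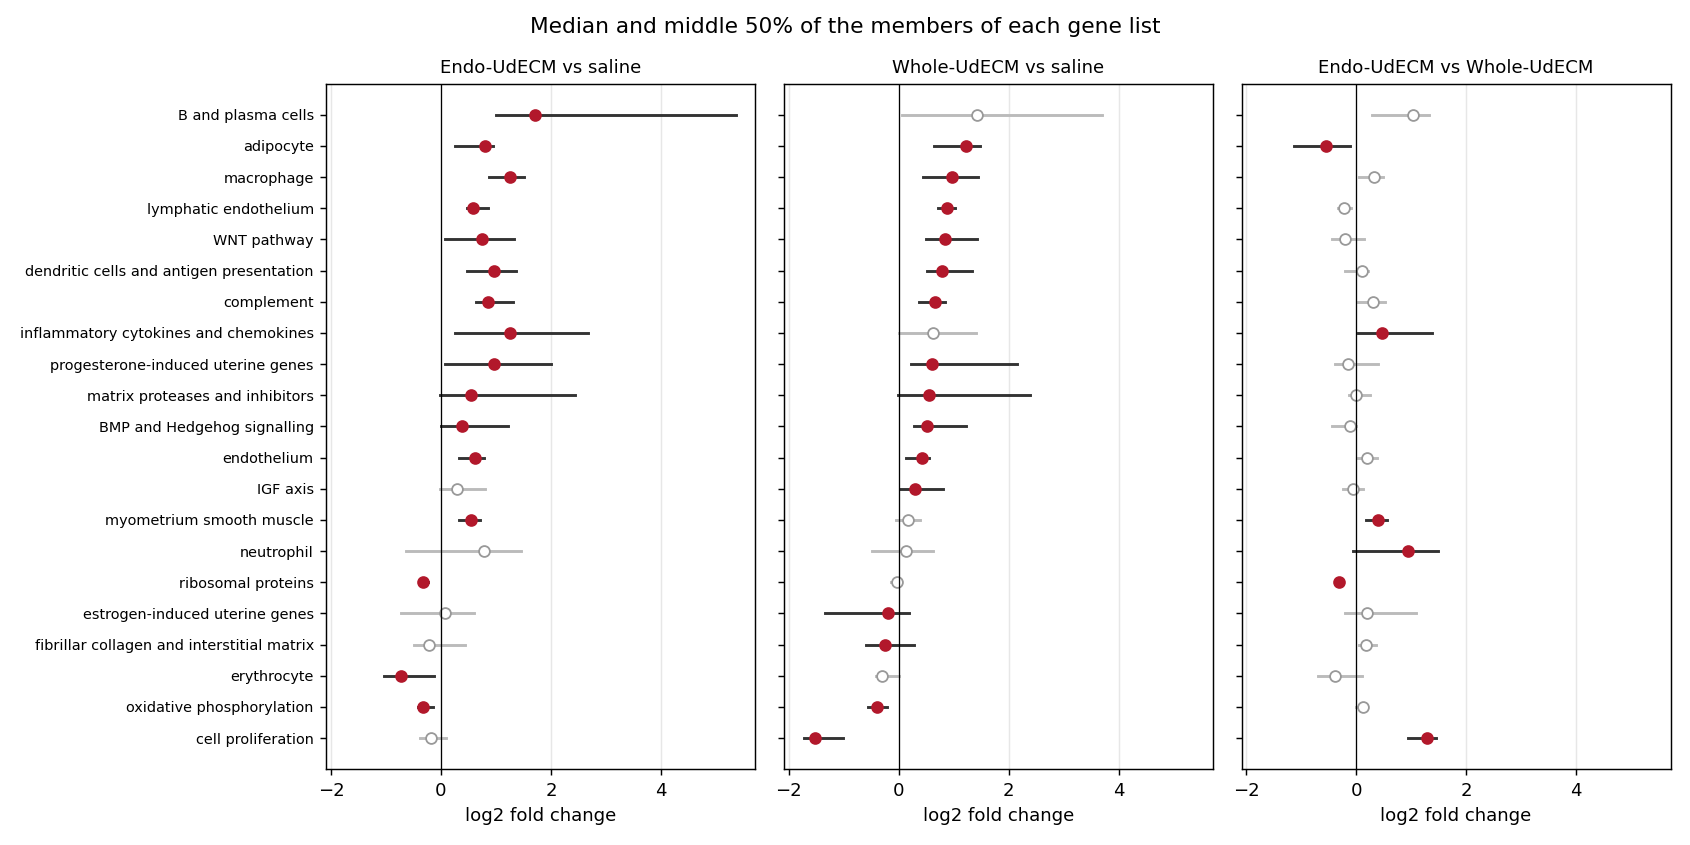
Median (points) and middle 50% (lines) of the log2 fold changes of the members of each gene list, in 3 comparisons, with filled points for lists that passed the set test with the preset correlation and open points for the others. The cell proliferation median was -1.51 in Whole-UdECM against saline and -0.17 in Endo-UdECM against saline, where it turned to 0.04 when scaled by library size alone and 0.26 without saline replicate 3. The line of B and plasma cells includes fitted values of genes at 0 in saline.

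Endo-UdECM was compared with Whole-UdECM to ask whether the 2 preparations differed. All 32 cell proliferation genes had estimates above 0 in Endo-UdECM against Whole-UdECM, with a median log2 fold change of 1.29 (adjusted p = 8.42e-42, camera with a preset correlation, and adjusted p = 0.68 with an estimated correlation). Of these, 24 were higher adjusted over the list alone and 0 over all genes. Cenpf had 148 ± 16.8 CPM in Endo-UdECM (SD, n = 2) and 67.8 ± 13.99 in Whole-UdECM (n = 3), a log2 fold change of 1.12 ± 0.21 (SE, adjusted p = 0.362). Mki67 had 1.32 ± 0.34 (adjusted p = 0.714). Smooth muscle genes of the myometrium were higher in Endo-UdECM by a median of 0.40, with 19 of 23 above 0 (adjusted p = 1.38e-05), a call lost without Whole-UdECM replicate 3, where the adjusted p of the list myometrium smooth muscle in Endo-UdECM vs Whole-UdECM was 0.0854. Ribosomal protein genes were lower by a median of -0.30, with 29 of 30 below 0 (adjusted p = 1.1e-06). Adipocyte genes were lower by a median of -0.55, with 16 of 19 below 0 (adjusted p = 0.0025), lost with the replicate block (0.0963) or without Endo-UdECM replicate 2 (0.292) or Whole-UdECM replicate 1 (0.125). With an estimated correlation the adjusted p was 0.886 for each of these 3 lists, and no member passed over the list alone or over all genes. Mean levels of each list overlapped between the preparations (centred log2 CPM). Smooth muscle lay at 0.28 and 0.34 in the Endo-UdECM libraries and at 0.37, 0.017 and -0.60 in the Whole-UdECM libraries. Ribosomal proteins lay at -0.24 and -0.16 against -0.18, 0.12 and 0.26, and the saline libraries at 0.37 and -0.19. Adipocyte genes lay at -0.45 and 0.39 against 1.02, 0.51 and 0.12.

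Neutrophil genes had a median of 0.95 in Endo-UdECM against Whole-UdECM with 9 of 12 above 0 (adjusted p = 0.0177, and 0.68 with an estimated correlation), and inflammatory cytokines and chemokines 0.48 with 20 of 26 above 0 (adjusted p = 0.0172, and 0.886 with an estimated correlation). No member of either list passed over the list alone or over all genes. Mean levels of inflammatory genes overlapped, at -0.070 and 1.38 in the Endo-UdECM libraries and 0.29, 0.24 and -0.52 in the Whole-UdECM libraries (centred log2 CPM). Neutrophil levels did not overlap, at 0.25 and 1.08 against -0.48, -0.20 and -0.34. The neutrophil peroxidase Mpo had 22 counts in Endo-UdECM and 0 in Whole-UdECM, the neutrophil granule gene Ngp had 0 counts in Endo-UdECM and 52 in Whole-UdECM, and the chemokine Cxcl5 had 2.37 ± 0.61 (SE, adjusted p = 0.714). The adjusted p of the list neutrophil in Endo-UdECM vs Whole-UdECM lost its call without Endo-UdECM replicate 3 (0.563), Whole-UdECM replicate 1 (0.0716) or saline replicate 1 (0.0513). The adjusted p of the list inflammatory cytokines and chemokines in Endo-UdECM vs Whole-UdECM lost its call without saline replicate 1 (0.0704), saline replicate 3 (0.05) or Whole-UdECM replicate 3 (0.0854), and its direction turned without Endo-UdECM replicate 3 (0.906).

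No single gene passed between the preparations (edgeR quasi-likelihood test), with 562 genes at an unadjusted p under 0.05 where chance gives 756.2. DESeq2 called 32, limma-voom 0 and limma-trend 0, and edgeR called 1 without Endo-UdECM replicate 2 and 1 without Endo-UdECM replicate 3. Groups did not overlap in 22.1% of tested genes, and chance gives 20%. The genes of lowest p that were higher in Endo-UdECM were the basal keratin Krt5, with 31.3 ± 31.3 CPM against 0.135 ± 0.234 (SD), the cell cycle repressor E2f7 (9.56-fold, adjusted p = 0.33), the keratin Krt15 (6.25-fold, 0.362) and Cenpf. Those lower were Cdo1 (3.41-fold, adjusted p = 0.33), Topaz1, a germ cell gene at 0 in Endo-UdECM and at least 42.6-fold lower, Amotl2 (3.27-fold, 0.515) and the granzyme Gzmc (7.78-fold, 0.622). Igfbp3 had a log2 fold change of -0.21 ± 0.36 and Igf1 0.11 ± 0.27 between the preparations. Plat had 98.5 CPM in Endo-UdECM and 104 in Whole-UdECM.

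**Figure D3:**
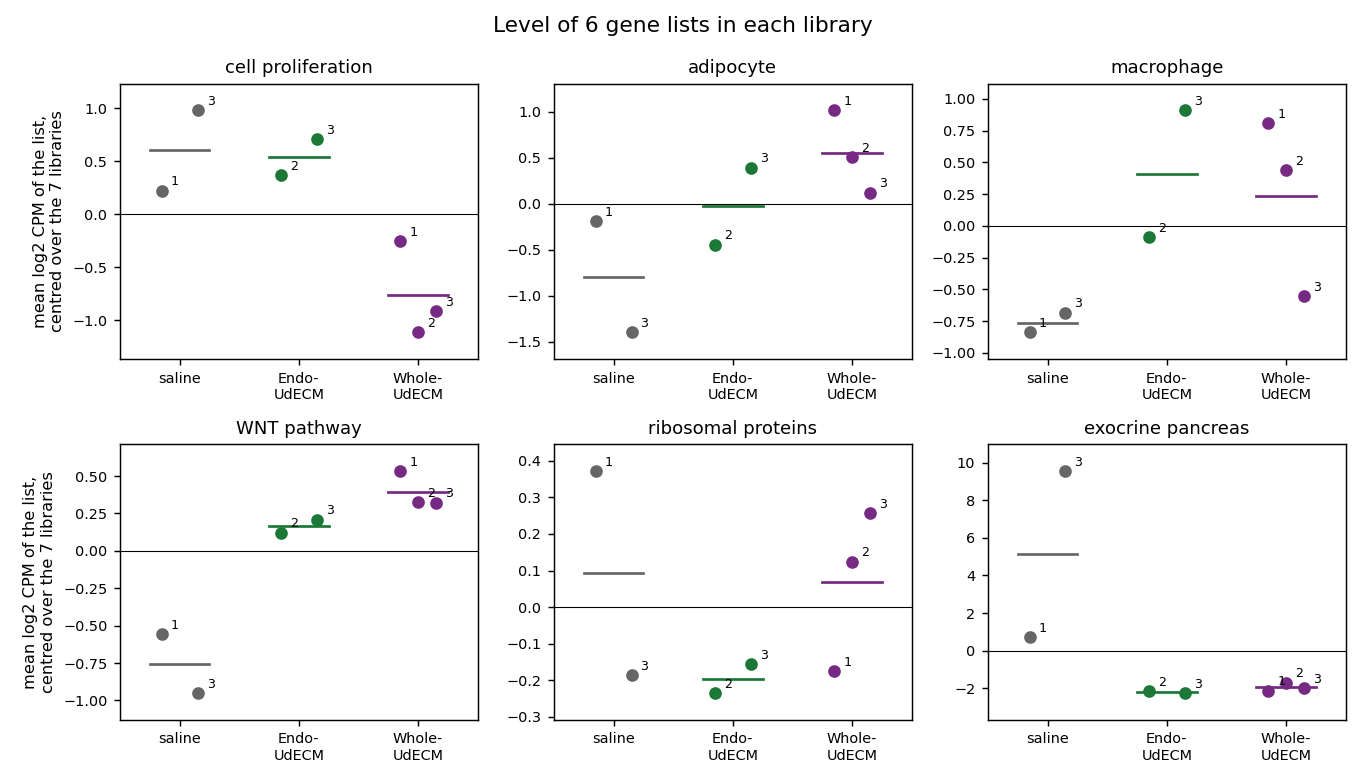
Mean log2 CPM of the members of 6 gene lists in each library, centred over the 7 libraries, with points numbered by replicate and bars at the group mean. Cell proliferation was at 0.37 and 0.71 in the Endo-UdECM libraries and at -0.26, -1.12 and -0.91 in the Whole-UdECM libraries, and exocrine pancreas genes stood highest in saline replicate 3.

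The mean of both preparations was compared with saline to describe the average response, which can rest on 1 preparation. Plat rose 7.46-fold (log2 fold change 2.90 ± 0.22, SE, n = 5 against 2, adjusted p = 0.000166), Igfbp3 11.4-fold (0.0169), Cldn1 10.9-fold (0.0157), Rassf10 10.1-fold (0.0315), Bambi 4.04-fold (0.0477) and Id3 3.18-fold (0.0157). Mgp (3.05-fold), Abca1 (2.69-fold) and the homeobox gene Msx1 (2.19-fold) rose as well, where Msx1 overlaps the listed transcript Msx1os. Falls were seen in Vaultrc5 (7.17-fold), Rn4.5s (5.49-fold), Gpr153 (4.08-fold), the cholesterol synthesis genes Msmo1 (3.46-fold) and Cyp51 (2.82-fold), the glycosyltransferase Galnt12 (3.05-fold), the matrix protein Spon1 (2.37-fold), and Sec11c (2.18-fold) and Sec61g (2.06-fold) of the secretory pathway. These were the 18 genes that passed, 9 higher and 9 lower, and 1990 genes had an unadjusted p under 0.05. In the simulated data this comparison gave a larger share of false calls than the threshold allows. Each of the 18 genes had all 5 UdECM libraries on 1 side of both saline libraries, as in 18.4% of all tested genes, where chance gives 9.52%. The count was 350 without saline replicate 1, 188 without saline replicate 3, 2 without Endo-UdECM replicate 2, 1 without Endo-UdECM replicate 3, 8 without Whole-UdECM replicate 1, 6 without Whole-UdECM replicate 2 and 57 without Whole-UdECM replicate 3.

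Gene lists in the mean comparison numbered 18 of 40 past the preset set test, 13 higher and 5 lower, among them macrophage (median 1.09, adjusted p = 3.34e-07), WNT pathway (0.80, 3.53e-06) and adipocyte genes (0.94, 1.94e-05) and, lower, cell proliferation (-0.78, 5.01e-11) and oxidative phosphorylation (-0.35, 7.04e-07). With an estimated correlation the adjusted p was 0.177 for the WNT pathway and 0.539 for the other 4. Of these 5 lists, WNT had 6, macrophage 1, cell proliferation 15, oxidative phosphorylation 3 and adipocyte 0 members passing adjusted over the list alone, against 0 over all genes in each. The adipocyte call was lost without saline replicate 3 (0.0903, median 0.60), and there the cell proliferation median was -0.38. Cell proliferation passed in Whole-UdECM against saline (median -1.51) and not in Endo-UdECM against saline (median -0.17, adjusted p = 0.267). Estrogen-induced genes had a median of -0.41 and a mean of -0.12 (adjusted p = 0.0238, and 0.593 with an estimated correlation), lost without saline replicate 3 (0.87, median 0.62), Endo-UdECM replicate 2 (0.229) or Whole-UdECM replicate 2 (0.0513). Ribosomal protein genes had a median of -0.19 (adjusted p = 0.00787, and 0.739 with an estimated correlation), which was 0.02 when scaled by library size alone, as the estrogen-induced median was -0.21 and that of oxidative phosphorylation -0.14. Without saline replicate 1 that list turned direction (0.299, median 0.086), without saline replicate 3 its median was -0.47, and it was lost without Whole-UdECM replicate 1 (0.104). Across the 4 comparisons none of the calls among these 40 lists held with an estimated correlation, and no called list differed in sign between its median, mean and test.

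The responses to both preparations were compared because each was measured against the same saline libraries. Plat was the 1 gene called in both with all libraries. Simulations of unchanged groups, described below, gave 0.25 such genes on average and 1 at most, so a count of 1 lies within their range. The number called in both in 1 direction was 84 without saline replicate 3 and 104 without saline replicate 1, fits with 1 saline library for which unchanged groups were not simulated. Over 15124 genes the log2 fold changes correlated with r = 0.80, where genes are not independent replicates, and 77.4% had the same sign. In 20 simulations of unchanged groups that share saline libraries, r was 0.56 on average (0.53 to 0.59) and 68.6% had the same sign. The covariance was 1.53 against 0.38 in the simulations, a difference of 1.15. A separate saline library as the control of each preparation was not tried. The simulations share the saline libraries but give each gene 1 spread in all groups, while the real saline pair differed more than the other pairs. Part of the excess can therefore still come from the shared controls.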

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

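The tests on the source of the pancreatic transcripts, on pancreatic RNA behind the secretory pathway and cell cycle genes, on dilution of the endometrium and on the estrous cycle were chosen only after the results were seen.

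For 6 gene lists the difference between the 2 preparations was itself tested and passed with the preset correlation, and each call was lost with an estimated correlation (lowest adjusted p = 0.68). The cell proliferation list was higher in Endo-UdECM than in Whole-UdECM (median log2 fold change 1.29 over 32 genes, adjusted p = 8.42e-42). Ribosomal protein genes were lower in Endo-UdECM (-0.30 over 30 genes, adjusted p = 1.1e-06). Smooth muscle genes of the myometrium were higher (0.40 over 23 genes, adjusted p = 1.38e-05). Adipocyte genes were lower (-0.55 over 19 genes, adjusted p = 0.0025). Inflammatory cytokines and chemokines were higher (0.48 over 26 genes, adjusted p = 0.0172). Neutrophil genes were higher (0.95 over 12 genes, adjusted p = 0.0177). Leaving out 1 library ended 4 of these calls, with the values given for each list between the preparations. Library levels of the ribosomal, smooth muscle, adipocyte and inflammatory lists overlapped between the preparations. Those of the cell proliferation and neutrophil lists did not overlap.

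Pancreatic transcripts stood out in saline replicate 3, where 26 of 26 exocrine pancreas genes found were at least 10-fold above the highest other library, led by Amy2a5 with 65655 counts, and where Ins1, Ins2 and Gcg together had 488 counts against 0 elsewhere, while 2 of the 26, Cela1 and Rnase1, had 5 to 69 counts in each of the other 6 libraries. Saline replicate 1 also had small counts of exocrine genes that were at 0 in both Endo-UdECM libraries, such as Cela2a (35), Amy2a5 (33) and Try4 (28). Pancreas tissue or its RNA in saline replicate 3 is a candidate source. The counts do not tell tissue taken with the uterus from RNA carried over later. The listed pancreas genes alone do not set the saline libraries apart. Without them the pair's chi-square per degree of freedom fell from 78.1 to 58.5, above the 17.3 to 37.6 of the other 4 pairs of 1 group. Pancreatic RNA of genes outside the lists was not removed. This test therefore cannot decide whether pancreatic material as a whole sets the pair apart. Against pancreatic RNA as the whole cause of lower secretory pathway genes in Whole-UdECM, the upper quartile of that list without saline replicate 3 was still -0.23, with 1 saline library left. The design names no group that would give pancreatic transcripts, so no biological explanation was tested.

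Cell cycle genes were lower in Whole-UdECM than in saline (median -1.51, adjusted p = 0.527 with an estimated correlation) and than in Endo-UdECM (adjusted p = 0.68 with an estimated correlation). Against pancreatic RNA in saline replicate 3 as the whole cause, the list's median without that library was -0.91 and its upper quartile -0.57, with 1 saline library left, and a part in the fall from -0.91 to -1.51 stays open. Against dilution of the endometrium by another tissue as the whole cause, the lower quartiles of the epithelium and stroma lists were -0.50 and -0.20, both above the cell cycle list's upper quartile of -1.01. A part of dilution in the fall stays open. Adipocyte genes had a median of 1.23 and smooth muscle genes 0.17 in Whole-UdECM against saline. A different stage of the estrous cycle cannot be told apart from the treatment: the upper quartile of the estrogen-induced list was 0.19 and the lower quartile -1.34, so its members went both ways, and stages are not given in the sources used here. An effect of the Whole-UdECM preparation on dividing cells, the difference the design names, may account for the pattern and stays open as an untested hypothesis.

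Some non-polyadenylated transcripts, Rn4.5s, Vaultrc5 and 4 histone genes, fell in Whole-UdECM against saline, and Rn4.5s took 0.403 and 0.314% of counts in saline and 0.0468 to 0.126% in UdECM, while the ribosomal RNA precursor Rn45s did not pass (adjusted p = 0.399). Less capture of RNA without a poly(A) tail in the UdECM libraries cannot be told apart from the treatment: 46 other small RNAs had a median log2 fold change of -0.74 in Whole-UdECM against saline (95% interval -1.17 to -0.25 from a bootstrap over genes, which are not independent), with 33 below 0, 13 above 0 and 0 called, and -1.11 in Endo-UdECM against saline (-1.51 to -0.52), with 37 below 0, 8 above 0 and 0 called. Library preparation dates are not given in the sources used here. The same explanation is argued against for the histone genes between the preparations, since the small RNAs had a median of -0.031 in Endo-UdECM against Whole-UdECM (-0.51 to 0.29) and the histone genes 1.37. A change in histone genes that follows the cell cycle genes may account for that part and stays open.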

How the results depend on the processing

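Among the tests of this part, those with the pancreas genes and Rn45s removed, the fit that is not robust, and the overlap without saline replicate 3 were chosen only after the results were seen. The call of Plat against saline held in 13 of 13 settings tried on single genes, with log2 fold changes of 2.65 to 3.08 in Endo-UdECM and 2.88 to 3.12 in Whole-UdECM. The overlap correlation was 0.84 over genes with a mean of at least 10 counts and 0.86 without saline replicate 3, but the value that unchanged groups give was simulated only for the overlap of 0.80, so neither shows that it is stable. Over all named genes, 3663 values kept their direction and side of the threshold, 191 passed where they had not, 197 no longer passed and 61 turned direction. Most of the values that kept their side were of genes not called, so the total does not show that calls are stable. Of the calls of named genes, 44 held by DESeq2. With the replicate block 16 held and 28 were lost, and without Whole-UdECM replicate 2 the numbers were 7 and 37. Replicate numbers showed no pairing of libraries: 5 same-numbered pairs of libraries had deviations from their group means that correlated across genes with r of -0.0564 to -0.000695, none over 0.1. Scaling by library size alone moved the median log2 fold change of all genes to 0.24, 0.22, 0.04 and 0.22 in Endo-UdECM against saline, Whole-UdECM against saline, Endo-UdECM against Whole-UdECM and the mean, from 0.02, 0.04, -0.0029 and 0.02 with TMM. Alternatives on a pseudocount apply only to tables without counts and were not run. Depth limits genes at or under 3 counts in a group. Folds of single genes at 0 in a group are given as bounds, except the highest values of Lif. List medians and quartiles hold fitted values.

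Counts of called genes moved as follows, and the cause was not tested except where fewer libraries or another set of genes is itself the change. In Endo-UdECM against saline the count of 1 became 20 with the replicate block, 25 with no filter beyond 1 count, 146 by DESeq2, 4 by limma-trend and 3 with only the groups compared, and ranged from 1 to 108 when 1 library was left out. For genes called Whole-UdECM vs saline the count of 48 was 33 with the replicate block, 12 of them among the 48. It became 30 with library size alone (20 higher and 10 lower, against 16 and 32), 170 with no filter beyond 1 count, 540 by DESeq2, 76 by limma-voom, 119 by limma-trend, 1 with only the groups compared and 17 when not robust, and ranged from 1 to 504 when 1 library was left out. Between the preparations the count of 0 became 32 by DESeq2 and ranged from 0 to 1 when 1 library was left out. For genes called mean of both UdECM vs saline the count of 18 became 33 with the replicate block, 38 with DESeq2 size factors, 103 with no filter beyond 1 count, 9 with a mean of at least 10 counts, 474 by DESeq2, 47 by limma-voom, 78 by limma-trend and 35 with the pancreas genes and Rn45s removed, and ranged from 1 to 350 when 1 library was left out. With library size alone it was 16 (12 higher and 4 lower, against 9 and 9). Of the 40 lists chosen in advance, 0 were called in each comparison with an estimated correlation. By fry the calls among these 40 numbered 0 in Endo-UdECM against saline and between the preparations, and 1 in Whole-UdECM against saline and in the mean. Leaving out 1 library gave 4 to 17 lists between the preparations (6 with all) and 10 to 18 in the mean (18 with all). The adjusted p of the list inflammatory cytokines and chemokines in Endo-UdECM vs Whole-UdECM ranged from 2.92e-06 to 0.906, and that of the ribosomal proteins in the mean from 1.15e-08 to 0.299, both turning direction at the upper end.

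Genes whose direction turned had not passed the test, and the cause was not tested. Ranges are over leaving out 1 library at a time. Hoxa10 had a log2 fold change of Hoxa10 in Endo-UdECM vs saline of -0.35 to 0.30, -0.12 with the replicate block, a log2 fold change of Hoxa10 in mean of both UdECM vs saline of -0.15 to 0.34, -0.059 with the replicate block, a log2 fold change of Hoxa10 in Whole-UdECM vs saline of -0.078 to 0.41 and a log2 fold change of Hoxa10 in Endo-UdECM vs Whole-UdECM of -0.50 to 0.15. Hoxa11 had a log2 fold change of Hoxa11 in Endo-UdECM vs saline of -0.62 to 0.32, 0.15 with library size alone, a log2 fold change of Hoxa11 in Whole-UdECM vs saline of -0.12 to 0.16, -0.18 with the replicate block, a log2 fold change of Hoxa11 in mean of both UdECM vs saline of -0.28 to 0.19, 0.19 with library size alone and a log2 fold change of Hoxa11 in Endo-UdECM vs Whole-UdECM of -0.68 to 0.26. Vegfa had a log2 fold change of Vegfa in Endo-UdECM vs saline of -0.58 to 0.57, 0.21 with library size alone, a log2 fold change of Vegfa in Whole-UdECM vs saline of -0.37 to 0.64, a log2 fold change of Vegfa in Endo-UdECM vs Whole-UdECM of -0.63 to 0.33 and a log2 fold change of Vegfa in mean of both UdECM vs saline of -0.41 to 0.60. Igf1 had a log2 fold change of Igf1 in Endo-UdECM vs Whole-UdECM of -0.10 to 0.31, -0.042 with the replicate block. Igfbp3 had a log2 fold change of Igfbp3 in Endo-UdECM vs Whole-UdECM of -0.53 to 0.046, 0.10 with the replicate block. Col3a1 had a log2 fold change of Col3a1 in Endo-UdECM vs Whole-UdECM of -0.17 to 0.10, 0.0088 with library size alone. Pcna had a log2 fold change of Pcna in mean of both UdECM vs saline of 0.0022 with library size alone and a log2 fold change of Pcna in Endo-UdECM vs saline of -0.038 to 0.40. Krt18 had a log2 fold change of Krt18 in mean of both UdECM vs saline of -0.18 to 0.042, 0.15 with library size alone and a log2 fold change of Krt18 in Whole-UdECM vs saline of -0.029 to 0.40. Vim had a log2 fold change of Vim in Endo-UdECM vs saline of -0.12 to 0.50 and a log2 fold change of Vim in Endo-UdECM vs Whole-UdECM of -0.29 to 0.33. Col1a1 had a log2 fold change of Col1a1 in Endo-UdECM vs saline of -0.79 to 0.096 and a log2 fold change of Col1a1 in mean of both UdECM vs saline of -0.89 to 0.0015. Lif had a log2 fold change of Lif in Whole-UdECM vs saline of -0.45 to 6.82 and a log2 fold change of Lif in mean of both UdECM vs saline of -0.091 to 7.18. Acta2 had a log2 fold change of Acta2 in Whole-UdECM vs saline of -0.46 to 0.67 and a log2 fold change of Acta2 in mean of both UdECM vs saline of -0.17 to 0.96. Cxcr2 had a log2 fold change of Cxcr2 in Endo-UdECM vs Whole-UdECM of -0.37 to 2.30. Esr1 had a log2 fold change of Esr1 in Endo-UdECM vs Whole-UdECM of -0.39 to 0.15. Pecam1 had a log2 fold change of Pecam1 in Endo-UdECM vs Whole-UdECM of -0.10 to 0.64. Rps18 had a log2 fold change of Rps18 in mean of both UdECM vs saline of -0.72 to 0.032. Rps20 had a log2 fold change of Rps20 in mean of both UdECM vs saline of -0.56 to 0.023. The highest values of Lif rest on a saline group at 0 and are fitted values, not bounds.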

Other observations

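The lists of cholesterol, histone and secretory pathway genes were written after the called genes had been seen and hold some of them, so their counts are not independent evidence. Cholesterol synthesis genes were lower in Whole-UdECM than in saline, with 24 of 25 estimates below 0 and a median log2 fold change of -1.16 (adjusted p = 2.14e-14, and 0.065 with an estimated correlation). Of these, 15 were lower adjusted over the list alone and 3 over all genes: Msmo1, Cyp51, a sterol demethylase at -1.82 (adjusted p = 0.0198), and Tmem97. Without saline replicate 3 the median was -0.57 and 2 genes of the list passed over all genes, and without saline replicate 1 the median was -1.46 and 8 passed. In Endo-UdECM against saline the median was -0.81 with 22 of 25 below 0 (adjusted p = 2.21e-08, and 0.108 with an estimated correlation), or -0.43 without saline replicate 3.

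Genes of protein folding and secretion in the endoplasmic reticulum had 33 of 35 estimates below 0 in Whole-UdECM against saline, with a median of -0.70 (adjusted p = 1.12e-19, and 0.0522 with an estimated correlation). Of these, 22 were lower adjusted over the list alone and 4 over all genes, among them Sdf2l1, a chaperone cofactor, at -1.82 (adjusted p = 0.0363), and Sec61g, a subunit of the protein channel into the endoplasmic reticulum, at -1.09 (adjusted p = 0.0367). Pancreatic transcripts made up 3.18% of saline replicate 3, and without that library the median was -0.47 with 3 genes passing over all genes, against 17 without saline replicate 1. Replication-dependent histone genes had 35 of 35 estimates below 0 with a median of -1.94 (adjusted p = 1.04e-21, and 0.0398 with an estimated correlation). The value of 0.0398 rests on adjustment over the lists written after the data were seen alone. Of the histone genes, 20 were lower adjusted over the list alone and 4 over all genes. Without saline replicate 3 their median was -1.77 and 0 passed over all genes, and without saline replicate 1 it was -2.09 and 6 passed. The median was -0.76 in Endo-UdECM against saline (adjusted p = 1.19e-06, and 0.108 with an estimated correlation), -0.49 without saline replicate 3 and -1.10 without saline replicate 1. Several histone genes are near-identical and share reads.

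Markers of the endometrium itself did not pass the set test in either preparation. Epithelial genes had a median of -0.16 in Endo-UdECM and 0.06 in Whole-UdECM against saline (adjusted p = 0.56 and 0.985), and stromal genes 0.02 and 0.12 (0.349 and 0.985). The epithelial mean was 0.10 and 0.14, above 0 where the test pointed down in both, and the stromal mean in Endo-UdECM was -0.027 with the test pointing down. Genes of implantation and decidualization had medians of 0.07 and 0.14 (0.319 and 0.371), and the TGF-beta pathway 0.22 and 0.10 (0.178 and 0.29). The interferon response had 0.53 and 0.03 (0.267 and 0.985), and immediate early and handling stress genes -0.17 and 0.16 (0.872 and 0.985). Across the samples Hoxa10, a homeobox gene of the uterus, had 211 ± 52.6 CPM in saline, 213 ± 66.5 in Endo-UdECM and 235 ± 52.9 in Whole-UdECM (SD, n = 2, 2 and 3).

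The p-values deposited by the authors were under 0.05 for 1140 of 23282 genes in Endo-UdECM over saline (646 higher, 494 lower), 1462 in Whole-UdECM over saline (593 and 869) and 998 in Whole-UdECM over Endo-UdECM (372 and 626). Adjusted here by Benjamini-Hochberg, 2, 0 and 4 of them were under 0.05. Chance gives a share of 0.05 of the rows tested. Of all 23282 rows, 1140 and 998 are below that share and 1462 is above it, but 5191 rows are 0 in all 7 libraries. For Plat the authors' table gives fold changes of 6.79 and 7.13 over saline.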
